A study of Sus scrofa with 6 samples.

How the data were processed

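RNA was extracted from 3 whole control embryos and 3 whole parthenogenetic embryos at embryonic day 21, treated with DNase, and made into libraries with a TruSeq RNA v2 kit, per the labels' protocols. This kit does not mark the strand of a read, so reads of overlapping genes on opposite strands cannot be told apart. Reads were processed with HISAT2 2.1.0 and SAMtools 1.9 against Sscrofa11.1, per the submitters' processing notes. The counting tool, its settings and the annotation release are not given in the sources used here.

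The authors' deposited table holds whole-number read counts per gene, with no normalization, for all 6 libraries. A deposited file per sample holds normalized signal values, which are whole reads multiplied by a factor per sample, from counts that differed slightly from the table. The factors recovered from the values were 1.05, 1.04 and 1.00 for control 1, 2 and 3 and 1.02, 0.959 and 0.916 for parthenote 1, 2 and 3. Reciprocals of DESeq2's size factors computed from these genes alone would be 1.06, 1.05 and 1.01, and 1.02, 0.939 and 0.900. How the authors derived their factors is not given in the sources used here. Divided by the factor, 100% of the normalized values came within 0.01 of a whole read. The recovered reads differed from the count table in 177 to 277 genes per library, by up to 103 reads, which added 0.0299% to 0.0570% to the library. The normalized files list 1190 genes.

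The count table used here has 1780 genes, of which 779 have a symbol and 1001 are known by their Ensembl identifier only. Symbols and positions were matched by symbol to RefSeq's table of the Sscrofa11.1 assembly, which placed 688 symbols, 687 of them on chromosome 9. Genes of other chromosomes were not analysed here. A CPM value is therefore a share of the chromosome 9 reads, and a library-wide change that acts on the whole chromosome would not show. Genes with a symbol held 77.7% of the counts. Counts of 0 in all libraries were found for 466 genes. The filter filterByExpr, with a minimum count of 10 and a minimum total of 15, left 807 genes with 99.9% of the counts, of which 657 have a symbol and 604 a position.

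Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, a robust quasi-likelihood fit of parthenote against control, and Benjamini-Hochberg adjustment over the 807 genes with a threshold of 0.05. Fold changes, SE and 95% intervals come from that fit, and CPM values were scaled with TMM. Floors of 3 counts, and the intervals given for the reads of single libraries, cover counting error only, since reads without molecular identifiers are not independent molecules. The biological coefficient of variation was 17.0%. Gene lists were compared with the remaining genes by camera in limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over the 5 lists with at least 3 tested members, and again with an estimated correlation and with fry. No pair of libraries within a group agreed within sampling noise, as a library deposited more than once would, with a chi-square of 6.98 to 143 per degree of freedom over the tested genes, so none were merged.

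The samples, gene lists, tests and most alternative settings were fixed before the data were examined. The rule for named genes took each tested member of the paternally and maternally expressed lists, the 10 largest rises and the 10 largest falls among called genes with a symbol, separated groups and at least 5 CPM in the higher group, and, from each other list, up to 3 called members or, where none was called, the member with the highest expression. A few further genes are named beside a count of 5 or fewer, or to describe a list or a region, and were chosen after their values were seen. Some genes that the rule selects, and a fixed list that rests on 1 of them, are not reported here. The alternative settings fixed then were DESeq2's size factors, library totals and upper-quartile factors as scaling, no filter and a filter of 10 counts in total, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, an adjusted p of 0.01 and glmTreat against a 1.5-fold change. Settings added after seeing the data were the authors' scaling factors in edgeR and in DESeq2, the reads recovered from the normalized values, and a fit without the most abundant gene.

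Controls and parthenotes carry the same replicate numbers in their titles, which do not say that a number marks a shared litter, batch or day. Over the 807 genes, the deviations from the group means correlated at 0.365, 0.272 and 0.147 between samples of the same number 1, 2 and 3. Control 3 and parthenote 2, of different numbers, correlated at 0.145. All same-number values were above 0.1, so the numbers were treated as pairing the samples in the blocked alternative, a pairing that comes from the data and not from the labels.

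The test was tried on counts simulated for the 807 genes with the means and library sizes of these samples, 200 of them given a change. The filter left 791 genes to test, 196 of them changed. For the comparison of parthenotes with controls it called 59.4% of 1.5-fold changes, 81.8% of 2-fold changes and 100% of 4-fold changes, and 4 of 595 unchanged genes. More calls loosen the adjusted threshold, and here 66 of the 4-fold changes alone were called, against 42 genes in the samples. The genes were also drawn independently, without the correlation between same-number samples, so the shares for 1.5-fold and 2-fold changes may be too high. The 95% interval held the true value for 95.2% of the genes. Content of G and C and gene length were not checked, since no genome sequence was used here.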

Results

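RNA was measured in 6 whole pig embryos of Landrace x Yorkshire x Duroc stock at embryonic day 21. Control embryos (n = 3) carried a maternal and a paternal genome. Parthenotes (n = 3) came from oocytes activated by electric pulses without sperm and grown in surrogate gilts, so all of their chromosomes were of maternal origin. The genes analysed here were those of chromosome 9, and each library held 1193714 to 1484193 reads counted in them. The total counts were 1397613, 1193714 and 1272753 in control 1, 2 and 3, and 1370624, 1364351 and 1484193 in parthenote 1, 2 and 3. Reads were counted in 1060 to 1107 genes per library. A floor of 3 counts corresponded to 2.02 to 2.36 CPM, counts per 1000000 of the counted chromosome 9 reads. The most abundant gene, ENSSSCG00000014726, has no symbol in the tables used here. It took 20.8%, 8.29% and 8.47% of the reads in control 1, 2 and 3, and 19.1%, 15.4% and 18.0% in parthenote 1, 2 and 3. Nothing in the labels says whether embryos of a group shared a litter or dam, so p-values measure the spread between these samples. How the control embryos were conceived is not described here. Differences in conception, handling, dam, sex or stage that went with the group cannot be told apart from the lack of a paternal genome.

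The series was designed to examine maternal and paternal gene expression, and the first comparison asked whether paternally expressed genes were lower in embryos without a paternal genome. PEG10, a retrotransposon-derived gene needed for formation of the mouse placenta, dropped from 30495 ± 4602 CPM in controls to 20.3 ± 9.11 CPM in parthenotes (SD, n = 3 each). SGCE, which encodes epsilon-sarcoglycan, dropped from 1073 ± 34.0 to 26.5 ± 16.1 CPM. The log2 fold change was -10.56 ± 0.30 (SE) for PEG10 and -5.35 ± 0.34 for SGCE, or 1510-fold and 40.8-fold lower. ZC3H12C and MAGI2, the other tested members of the list, had log2 fold changes of 0.10 ± 0.15 and 0.10 ± 0.16. The list holds genes known as paternally expressed in human, mouse, pig or other mammals. With 313 to 518 counts per parthenote, ZC3H12C and MAGI2 were not expressed from a paternal copy alone in these embryos.

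In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 807 genes, the adjusted p was 1.76e-06 for PEG10 and 3.34e-05 for SGCE, and 0.763 and 0.770 for ZC3H12C and MAGI2. Of the 49 genes in the list of paternally expressed genes, 4 were measured, 2 fell and 0 rose, and 2 passed when adjusted over the list alone. Against the other genes, the 4 members gave a camera p of 7.00e-13 toward lower values (adjusted p = 3.50e-12 over 5 lists). The adjusted p was 0.00886 when the correlation between genes was estimated. These p-values rest on PEG10 and SGCE and not on the list as a whole, since ZC3H12C and MAGI2 lay above 0. The median log2 fold change of the list was -2.63 and its mean -3.93, both carried by PEG10 and SGCE.

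**Figure D1:**
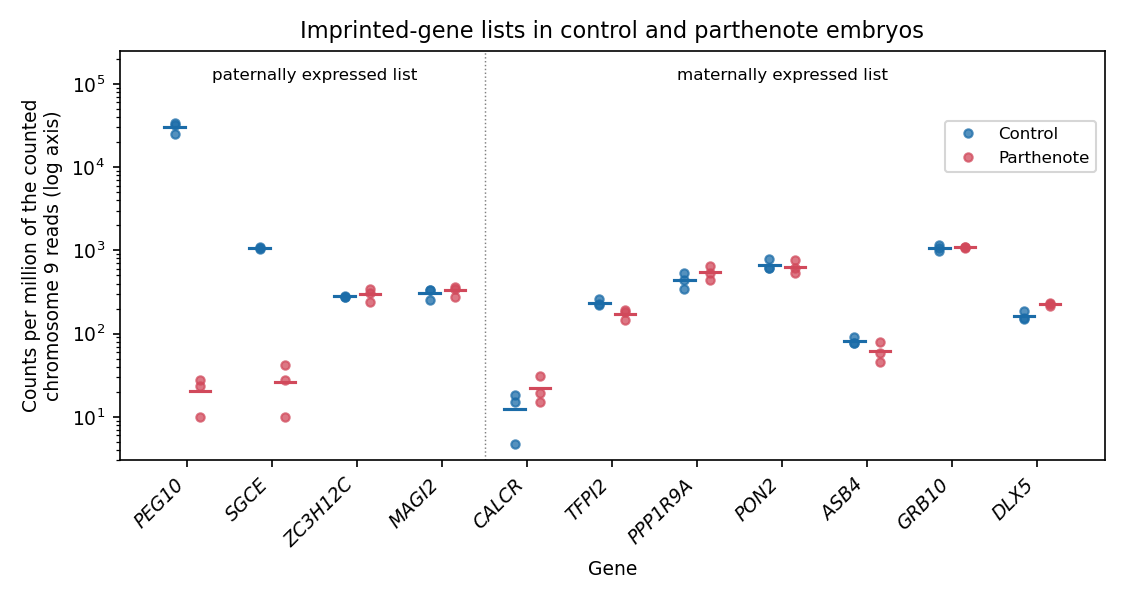
CPM of the counted chromosome 9 reads (log axis) of each tested gene of the paternally and maternally expressed lists, with a point per embryo and a bar at the mean of each group (n = 3). PEG10 and SGCE lay lower in each of the 3 parthenotes than in any control, while no maternally expressed gene passed the test.

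PEG10 and SGCE are neighbours on chromosome 9 of Sscrofa11.1. SGCE spans positions 74402714 to 74473904 and PEG10 74474121 to 74486983, with 216 bp between them, so their annotated spans do not overlap. Within 2 Mb on either side, a window chosen after the values were seen, 18 other genes were tested. In edgeR's test 0 of these 18 passed, and 4 had an unadjusted p under 0.05. Their log2 fold changes ran from -0.44 for TFPI2 to 0.80 for CALCR, with a median of 0.06, 11 above 0 and 7 below. COL1A2, which encodes a collagen I chain and lies at 74174484 to 74210407, had 45264 ± 1636 CPM in controls and 45407 ± 4091 CPM in parthenotes. Its log2 fold change was 0.00 ± 0.12.

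**Figure D2:**
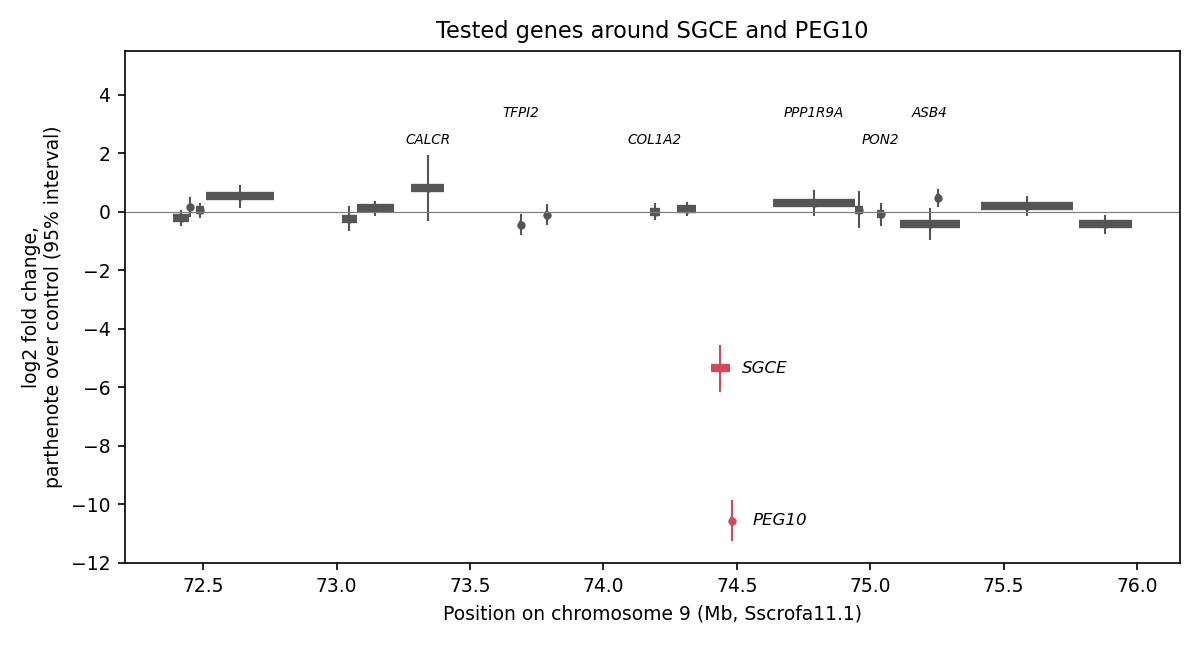
Log2 fold change, parthenote over control, of the 20 tested genes within 2 Mb of SGCE and PEG10, against position on chromosome 9 of Sscrofa11.1. Horizontal bars span each gene, vertical lines are 95% intervals, and the 2 genes past the threshold, SGCE at -5.35 and PEG10 at -10.56, are in red.

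The second comparison asked whether maternally expressed genes differed in embryos with only maternal chromosomes. No member of this list passed the test. GRB10, an adaptor of growth factor receptors, had 1076 ± 89.0 CPM in controls and 1087 ± 29.9 CPM in parthenotes, a log2 fold change of 0.01 ± 0.08 with a 95% interval of -0.18 to 0.21. DLX5, a homeobox gene, had 163 ± 19.5 CPM in controls and 224 ± 10.8 CPM in parthenotes, higher in 3 of 3 parthenotes, with a log2 fold change of 0.46 ± 0.13. TFPI2, a protease inhibitor gene, had a log2 fold change of -0.44 ± 0.15, and ASB4 one of -0.43 ± 0.22. The values for CALCR (the calcitonin receptor), PPP1R9A (neurabin) and PON2 (a paraoxonase) were 0.80 ± 0.48, 0.30 ± 0.19 and -0.09 ± 0.16.

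Of the 48 genes in the list of maternally expressed genes, 8 were measured and 7 tested. PON3 had 1 read over all libraries and was not tested. In edgeR's quasi-likelihood test 0 of the 7 passed, with adjusted p-values from 0.0946 for DLX5 to 0.949 for GRB10, and 2, DLX5 and TFPI2, had an unadjusted p under 0.05. Adjusted over the list alone, 0 passed. DESeq2 and limma-voom also gave 0, and DESeq2 with the authors' scaling factors gave 1, DLX5, at an adjusted p of 0.0411 (0.0411 to 1.00 over the 20 alternatives). The upper end came from glmTreat, which asks whether a change exceeds 1.5-fold. In log2 fold change 4 members lay above 0 and 3 below, the median was 0.01, and the camera p was 0.688. CALCR, with only 6 to 44 counts per library, had the largest SE of the list.

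Across all tested genes of the chromosome, 42 of 807 differed between parthenotes and controls, of which 29 fell and 13 rose. Which of these changes came from the lack of a paternal genome was not tested. Beyond PEG10 and SGCE, the largest falls by the naming rule included POU2F3, KCNJ1, NHERF4 and SCIN. KCNJ1, the potassium channel ROMK of renal tubules, dropped from 567 ± 26.7 to 80.9 ± 11.7 CPM. POU2F3, a transcription factor of epidermis and tuft cells, dropped from 96.9 ± 10.5 to 6.77 ± 3.46 CPM (SD, n = 3 each), and NHERF4, a scaffold protein gene, from 108 ± 7.34 to 22.1 ± 6.54 CPM. SCIN, which encodes the actin-severing protein scinderin, dropped from 471 ± 69.8 to 119 ± 7.96 CPM.

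The log2 fold changes were -3.82 ± 0.33 for POU2F3, -2.81 ± 0.14 for KCNJ1, -2.28 ± 0.23 for NHERF4 and -1.99 ± 0.14 for SCIN. Their adjusted p-values in edgeR's quasi-likelihood test were 5.89e-05, 3.73e-06, 2.97e-04 and 3.68e-05. POU2F3 lies at 47376852 to 47458265, KCNJ1 at 55779020 to 55812761 and SCIN at 82103271 to 82185254 of chromosome 9, outside the window around SGCE and PEG10. GPNMB, a transmembrane glycoprotein gene, fell by 1.43 on the log2 scale (adjusted p = 0.0175). PLET1, a placenta-expressed gene, fell by 2.76 with a 95% interval of -4.20 to -1.32 (adjusted p = 0.0264), on 12, 20 and 18 counts in controls and 2, 5 and 1 in parthenotes. Among genes without a symbol, ENSSSCG00000015084, chosen after its values were seen, had the largest fall, with a log2 fold change of -4.13 ± 0.31. The call of PLET1 was lost without control 2, control 3, parthenote 1 or parthenote 3 (adjusted p 0.0588 to 0.118), and without parthenote 2 its log2 fold change was -3.58. That of GPNMB was lost without control 1, control 2 or parthenote 3 (0.0700 to 0.0760), and without a filter on low counts (0.110).

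Fewer genes rose, and by smaller amounts. ASNS, which encodes asparagine synthetase, rose from 936 ± 50.2 to 2199 ± 206 CPM, and APOC3, which encodes apolipoprotein C-III, from 1917 ± 252 to 4059 ± 1149 CPM, or 2.35-fold and 2.12-fold. NRCAM, a neuronal cell adhesion molecule, rose by 0.64 ± 0.13 on the log2 scale, MAP6, a microtubule-stabilising protein gene, by 0.55 ± 0.09, FEZ1, an axonal transport adaptor gene, by 0.49 ± 0.09, ROBO3, an axon guidance receptor gene, by 0.48 ± 0.10, and AMPH, which encodes the synaptic protein amphiphysin, by 0.47 ± 0.10. PLEKHB1 rose by 0.54 ± 0.08, PGM2L1 by 0.47 ± 0.11, and IL19, a cytokine gene at 3 to 6 counts in controls and 16 to 21 in parthenotes, by 1.85 ± 0.44.

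In edgeR's quasi-likelihood test the adjusted p was 4.90e-05 for ASNS, 0.00639 for PLEKHB1, 0.00900 for MAP6, 0.0126 for FEZ1 and 0.0178 for APOC3. It was 0.0213 for NRCAM, 0.0242 for ROBO3, 0.0283 for AMPH, 0.0393 for IL19 and 0.0475 for PGM2L1. ASNS and PLEKHB1 passed in each of the 6 fits with a library left out. The call of APOC3 was lost without control 1, 2 or 3 (adjusted p 0.0567 to 0.0730), that of FEZ1 without control 2 or 3 (0.0699 to 0.0761), and that of MAP6 without control 3 (0.0505). NRCAM lost its call without control 2, parthenote 2 or parthenote 3 (0.0710 to 0.0843), and ROBO3 and AMPH without control 2, control 3, parthenote 2 or parthenote 3 (0.0765 to 0.131). PGM2L1 was lost without any library but parthenote 1 (0.0742 to 0.157), and IL19 without any of the 6 (0.0579 to 0.169), with the replicate number as a block (0.0684) and in DESeq2 (0.0612). With library totals as the only scaling NRCAM, MAP6, ROBO3, AMPH and PGM2L1 did not pass (0.0515 to 0.209). PGM2L1 also missed the threshold with DESeq2's size factors (0.0501), upper-quartile factors (0.0551) and limma-voom (0.0528).

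**Figure D3:**
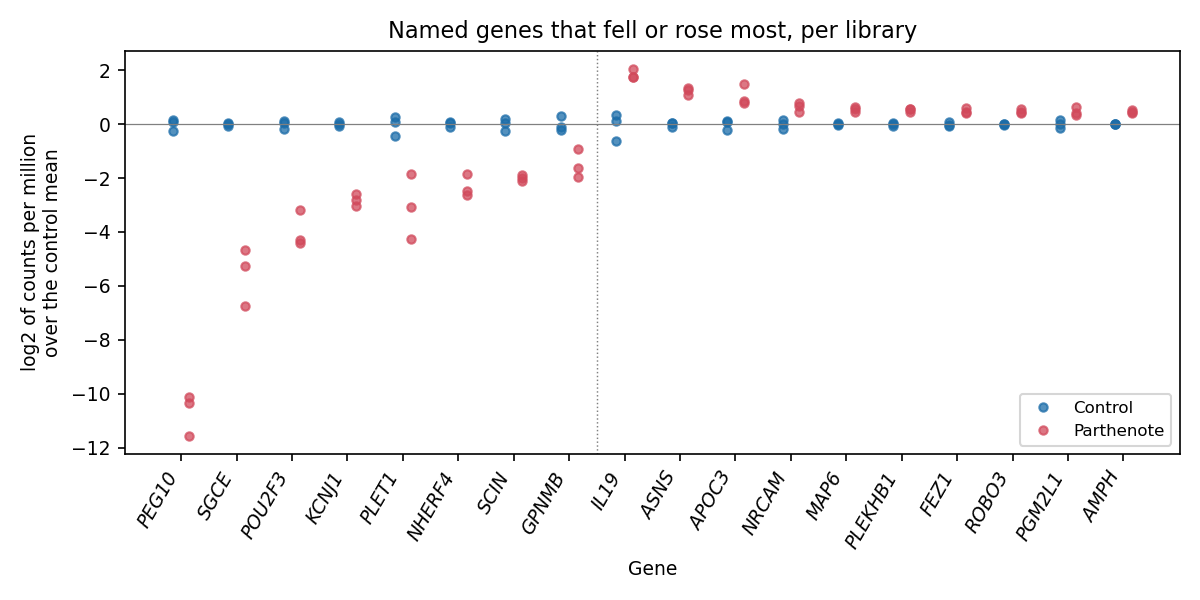
Log2 of CPM over the control mean, with a point per embryo, for 8 of the genes with the largest falls and the 10 with the largest rises among the called genes with a symbol. In each of these genes the 3 parthenotes lay apart from the 3 controls, with falls from PEG10 at -10.56 to GPNMB at -1.43 and rises from IL19 at 1.85 to AMPH at 0.47.

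The 42 called genes all had 3 libraries of a group above the 3 of the other. This was so for 226 of the 807 tested genes (28.0%), where chance gives 10%. An unadjusted p under 0.05 was found for 175 genes, where 40.4 are expected if none differed. Among the called genes 20 had a log2 fold change of at least 1 in size, 17 of them lower. The split of 13 higher and 29 lower became 5 and 27 with library totals as the only scaling. The count was 42 without control 1, 17 without control 2, 18 without control 3, 55 without parthenote 1, 26 without parthenote 2 and 22 without parthenote 3. It was 17 at an adjusted p of 0.01, 13 with glmTreat against a 1.5-fold change, 65 in DESeq2, and 68 in DESeq2 with the authors' scaling factors.

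The remaining gene lists covered tissues, cell types and pathways of a whole embryo. Of the liver and yolk sac genes, APOC3 rose, while APOA1 and APOA4 did not pass, with log2 fold changes of 0.11 ± 0.24 and 0.48 ± 0.81. Of the stress genes, ASNS rose, ATF3 had a log2 fold change of 0.21 ± 0.37 and the chaperone gene HSPA8 one of -0.51 ± 0.16. Of 2 tested genes of oxidative phosphorylation, NDUFA4 fell by 0.84 on the log2 scale (adjusted p = 0.0242 in edgeR's test). The call of NDUFA4 was lost without any library but parthenote 1 (adjusted p 0.0505 to 0.0907), and its reads are uncertain, since RefSeq places a copy of it on another chromosome. HBB, the only measured gene of the red cell list, had 1388 ± 612 CPM in controls and 281 ± 256 CPM in parthenotes. Its log2 fold change was -2.30 ± 0.76 (adjusted p = 0.189 in edgeR's test), lower in 3 of 3 parthenotes, and globin genes can share reads. HBB passed without parthenote 2, at a log2 fold change of -3.37 (adjusted p = 0.00550), and in DESeq2 (0.0454), with a range of 0.00550 to 1.00 over the 20 alternatives, the upper end from glmTreat against a 1.5-fold change.

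Among the 3 remaining lists with at least 3 tested members, 0 passed camera with a correlation of 0.01, and 0 with an estimated correlation. The camera p was 0.0339 (adjusted p = 0.0847) for the stress genes, 0.167 (adjusted p = 0.278) for the liver and yolk sac genes, and 0.995 for extracellular matrix genes COL1A2, LAMB1 and LAMC1. The stress list passed in fry (adjusted p = 0.0264), which does not compare a list with other genes, and in camera without parthenote 3 (adjusted p = 0.0220). With an estimated correlation its adjusted p was 0.246. Adjusted over the list alone, 2 stress genes, 1 liver and yolk sac gene and 0 matrix genes passed. The 2 stress genes were ASNS, which lay above 0, and HSPA8, which lay below 0. The upward direction of the stress list was thus carried mainly by ASNS.

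The lists with fewer members gave counts only. Of the placental genes PEG10, which is also in the paternal list, fell, and the other tested one did not pass. ESAM, an endothelial adhesion gene, had a log2 fold change of -0.42 ± 0.11 (adjusted p = 0.0677 in edgeR's test), and passed in DESeq2 (adjusted p = 0.0149, with 0.0149 to 1.00 over the 20 alternatives, the upper end from glmTreat against a 1.5-fold change). The values were 0.15 ± 0.08 for MYOG, the muscle regulator myogenin, 0.24 ± 0.31 for PHOX2A of autonomic neurons, and 0.08 ± 0.11 for the mitotic gene CENPF. They were -0.03 ± 0.13 for EGFR, 0.14 ± 0.12 for WNT11 and -0.02 ± 0.08 for EZH2, and none of these passed in edgeR's test. Adjusted over the list alone, 2 genes passed in the placental, limb and oxidative phosphorylation lists, 1 in the red cell and endothelial lists, and 0 in the skeletal muscle, neural crest, cell cycle, insulin-like growth factor, WNT and imprint maintenance lists. The red cell list had 1 tested gene, and the placental, limb, oxidative phosphorylation and endothelial lists had 2 each. Such values are thus unadjusted p-values or close to them, with no adjustment across lists. CD3E of the immune list and PGR of the uterine list had too few reads to test. Genes of the Y-linked, X-inactivation, heart, neural, HOX, apoptosis, hypoxia and mitochondrial genome lists were not analysed here, so the labels could not be checked against XIST or the Y chromosome.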

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

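The alternatives with the authors' scaling factors, the recovered reads, and without the most abundant gene were added after seeing the data, as were all tests of splits. Of the 42 called genes, 27 (4 higher, 23 lower) passed under each of 11 alternative settings with 6 libraries at a threshold of 0.05. These were drawn from the scalings, filters, count sources, tests and the block, and left out glmTreat against a 1.5-fold change. Only 13 of the 42 (1 higher, 12 lower) passed glmTreat, so many of the 27 did not. PLEKHB1, APOC3, FEZ1 and NDUFA4 were among the 27 that did not pass it. In each fit with a library left out, 15 of the 27 (2 higher, 13 lower) passed also. No named gene that passed changed sign.

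The count of called genes moved by over 1.5 times to 65 in DESeq2, 68 in DESeq2 with the authors' scaling factors, 17 at an adjusted p of 0.01 and 13 with glmTreat against a 1.5-fold change; the last 2 are stricter by construction, and for DESeq2 the cause was not tested. Leaving out a library gave 42 called genes without control 1, 17 without control 2 and 18 without control 3. It gave 55 without parthenote 1, 26 without parthenote 2 and 22 without parthenote 3, so fewer samples alone do not account for the drops. The libraries numbered 1 were least like the others of their group. The chi-square per degree of freedom was 141 and 143 for control 1 against control 2 and 3, and 6.98 between control 2 and 3. For parthenote 1 it was 61.0 and 52.8, and 21.1 between parthenote 2 and 3. Why the count depended on the library was not tested. With the replicate number as a block 55 genes were called, 41 of them among the 42; IL19 lost its call there, and the block ended no other call of a named gene or list. Other scalings and filters gave 32 to 55, and the recovered reads gave the same 42 genes.

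PEG10 and SGCE passed in every setting and every fit with a library left out, so the count for the paternal list was 2 throughout. That of the maternal list was 0 except with the authors' scaling factors in DESeq2, where it was 1 (DLX5), and the cause was not tested. In that setting DESeq2 gave no adjusted p for 47 of the 807 genes, against 0 with its own size factors. The adjustment there thus ran over fewer genes. The number of other lists past the set test, run also with the block, an estimated correlation, fry and each library left out, was 1 in fry and 1 without parthenote 3, the stress list each time, and 0 in the rest of these, so 0 to 1 over the fits with a library left out.

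The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 42 genes and the highest other 0, with 2 against 0 for the paternal list and 0 against 0 for the maternal list and for the other lists. Every other split puts parthenotes and controls in the same group, so the real difference widens the spread within groups. Counts of 0 there therefore say little of chance. The number of splits with a result as large, the real one included, was 1, 1, 10 and 10. Of the 10 splits, 4 part all 3 same-number pairs, the real one among them, and the other ones of these called 0 genes. Low counts limited CALCR, PLET1 and IL19, and CD3E, PGR and PON3 could not be tested.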

Other observations

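All tests below were chosen after the results were seen. The lists of kidney, surface epithelium, neuronal and mitochondrial genes were written after the most changed genes of the chromosome had been looked at, and leave out genes not reported here, so they are descriptions of these embryos and not independent evidence. Among further genes that fell was ST14, which encodes the protease matriptase of epithelia, with a log2 fold change of -1.40 ± 0.13 (edgeR adjusted p = 1.36e-04). Of 16 tested genes of surface epithelium, 3 fell (POU2F3, PLET1 and ST14) and 0 rose, 10 lay below 0 and 6 above, the median log2 fold change was -0.17, and the camera p was 0.00199, or 0.0684 with an estimated correlation. Of 23 tested mitochondrial genes, 3 fell and 0 rose, 18 lay below 0 and 5 above, and the camera p was 0.00334, or 0.412 with an estimated correlation.

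A few reads of PEG10 and SGCE were left in the parthenotes. PEG10 had 36, 33 and 15 counts in parthenote 1, 2 and 3, a mean of 0.0667% ± 0.0299 of the control level (SD, n = 3), and SGCE had 55, 14 and 41 counts, or 2.47% ± 1.5. Carry-over of reads from control libraries in 1 proportion would leave the same percentage of both genes. The SGCE percentage was at least 12.1 times that of PEG10 in each parthenote, with counting intervals apart. That argues against carry-over as the whole source of the SGCE reads, but the PEG10 reads could still be carry-over. Tissue of the surrogate dam could not be weighed well: PGR, the only uterine marker on the chromosome, had 0 reads in the 3 parthenotes and 6 in the controls, too near the floor to decide. Residual transcription from the maternal chromosomes and reads of similar sequence elsewhere in the genome also remain as hypotheses, and neither was tested.

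The largest falls spread well beyond SGCE and PEG10. Of 7 tested kidney genes, 3 fell, KCNJ1 and NHERF4 among them, and 0 rose, 4 lay below 0 and 3 above, and the median log2 fold change was -0.13 against a mean of -0.75. The camera p was 2.65e-06, or 0.00823 with an estimated correlation. Since this list was written with the changed genes in view, it does not decide whether the share of kidney tissue differed, and a difference in developmental stage was not tested.

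Genes of neurons were among the rises, at smaller sizes. Of 42 tested neuronal genes, 5 rose and 0 fell, 36 lay above 0 and 6 below, and the median log2 fold change was 0.35 (camera p 9.06e-07, or 0.196 with an estimated correlation). The neuronal list too was written with the changed genes in view and does not decide whether the share of nervous tissue differed. Under 4 other scalings each of the 10 largest rises kept at least 92.8% of its log2 fold change, but these scalings moved the median of all tested genes only by -0.03 to 0.02, so they say little of scaling as a cause. With library totals as the only scaling 5 of the 10 lost their call, where their log2 fold changes were 0.46 to 0.62, against 0.47 to 0.64, while their SE grew from between 0.09 and 0.13 to between 0.12 and 0.17.

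Parthenotes carry only maternal copies of each gene, so a gene expressed from the maternal copy alone might be doubled, a log2 fold change of 1. For 6 of the 7 tested members of the maternally expressed list the 95% interval lay below 1, which argues against expression in proportion to the number of maternal copies for these genes in whole embryos; CALCR was the exception. Many genes of this list are imprinted only in some tissues or species, and whether they are imprinted in the pig embryo at this age was not tested.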
